A study of Homo sapiens with 5 samples.

How the data were processed

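RNA was sequenced from 5 cultures of C4-2 cells, a human prostate cancer line that responds to androgen. Per the labels, the cultures were mock-treated or received a non-targeting control siRNA (siCont), an siRNA against EAF2 (siEAF2), an siRNA against TP53 (sip53) or both (siEAF2+sip53). Knockdown lasted 24 h, and the synthetic androgen R1881 was then added at 2 nM for 48 h. Each group holds 1 library. The labels give total RNA, a stranded total RNA library kit and an Illumina HiSeq instrument. Their extraction text names testes as the source, while every other field names the prostate cell line.

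The authors deposited 1 table per library with a row for each of 178136 transcripts. Per the file headers and the submitters' processing notes, these are estimated counts and TPM (a length-normalized transcript abundance) from Salmon 0.7.2. The notes also name GRCh38 and edgeR 3.18.1. The transcript set, the library type setting and the read filters are not given in the sources used here. Deposited estimated counts are not whole numbers and summed to 17533545 reads in mock, 17809851 in siCont, 17998132 in siEAF2, 17320870 in sip53 and 18719390 in siEAF2+sip53. The deposited TPM values were used only in alternatives.

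Transcripts were matched by identifier, without version, to GENCODE release 29 on GRCh38, and 162453 of 178136 had a gene there. These held between 97.81% and 97.89% of the reads of each library. The rest, which may include transcripts of alternate haplotypes, was left out. Estimated counts were summed over 35075 genes and rounded to whole numbers. Salmon divides reads that match several transcripts, so genes with near-identical copies have uncertain counts. For each gene, the share of 31-base words of its transcripts that also occur in another gene was computed. Genes with more than 20% shared words, and genes in regions with alternate haplotypes (chromosome 6 from 28 to 34 Mb, chromosome 17 from 45 to 47 Mb, chromosome 19 from 54 to 56 Mb), are called genes with shared or alternate-haplotype sequence. This class was defined after the data were examined.

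With 1 library per group there is no replicate check. The main tests used the factorial layout: an additive edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3) with EAF2 siRNA and TP53 siRNA as factors was fitted to the 4 siRNA libraries. It leaves 1 residual degree of freedom per gene, which is the departure from additivity, and edgeR moderates it across genes (prior degrees of freedom 5.33). The p-values therefore measure an effect against non-additivity between single libraries, not against the spread between replicate cultures, and a true interaction counts as noise. Normalization was by TMM, low genes were removed by filterByExpr, and Benjamini-Hochberg adjusted p below 0.05 was called. Each log2 fold change has a standard error (SE) derived from the F statistic. Ratios between single libraries are log2 ratios of TMM-scaled CPM (counts relative to library size) with a prior count of 2, over genes with a mean of at least 1 CPM, and a size of at least 1 on the log2 scale was counted. They have no p-value. Intervals on ratios of reads are exact 95% intervals. Intervals and the floor of 3 reads cover counting error only, since reads without molecular identifiers are not independent molecules.

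On simulated libraries with 200 changed genes, the EAF2 model recovered 59.7% of 1.5-fold, 80.6% of 2-fold and 93.9% of 4-fold changes over 15097 genes, and 6 of its 162 calls were false. For the TP53 model over 15096 genes these were 59.7%, 76.1% and 92.4%, with 9 false of 161 calls. The simulated libraries were additive, so these rates do not cover interactions. Each simulated gene had the variance fitted for its expression level, without further variation between genes, so the rates may be optimistic for the real libraries.

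Before the data were examined, 20 gene lists were fixed: p53 targets, androgen response, STAT3 targets, cell cycle, super elongation complex, interferon response, hypoxia and angiogenesis, unfolded protein and integrated stress response, cholesterol synthesis, DNA repair, epithelial to mesenchymal transition, luminal prostate, basal prostate, neuroendocrine, testis germ cell, fibroblast and stroma, immune cell, replication-dependent histones, ribosomal proteins and mitochondrial genome. A list's median was placed among 10000 random lists of equal size matched on mean expression in 20 bins, as a description of these libraries. Of 200 simulated lists with no effect, 9 lay outside the central 95%. Simulated genes varied independently, while members of a real list can vary together, so this rate need not hold for real lists. In mock over siCont, without a targeting siRNA, p53 targets lay at percentile 0, and STAT3 targets and stress-response genes at 99.7. Cell cycle and interferon genes lay at 98.6 and the mitochondrial genome at 98.5. The other lists placed lay within the central 95%. The design, the alternatives and the rule for named genes were also fixed before the data were examined. The rule takes EAF2 and TP53; for each siRNA effect, the 10 largest rises and falls with a symbol among called genes of the same sign in both backgrounds; for each library against siCont, the 6 highest and 6 lowest genes with a mean of at least 5 CPM; the 5 highest and 5 lowest departures from additivity; and up to 4 members with the largest change in each list described.

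Alternatives were DESeq2 size factors or total counts, other low-count filters, DESeq2 1.42.0 and limma 3.58.1 in place of edgeR, length-scaled TPM, mock in place of or beside siCont, leaving out each library with mock added, leaving out abundant genes, and other prior counts. Leaving out genes with shared or alternate-haplotype sequence was added after the data were examined.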

Results

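Gene expression was measured by total RNA sequencing in C4-2 prostate cancer cells after knockdown of EAF2, of TP53 or of both, under androgen. EAF2 is an androgen-induced partner of the ELL transcription elongation factors, and TP53 encodes the tumour suppressor p53. The series asks what each knockdown does alone and what the concurrent knockdown does. The 5 groups, mock, siCont, siEAF2, sip53 and siEAF2+sip53, had 1 library each, so no value below has a replicate error. Libraries held 17320870 to 18719390 estimated reads and between 21343 and 21888 genes with at least 1 read. Mitochondrial genes took 19.16% of reads in mock, 18.46% in siCont, 17.14% in siEAF2, 19.76% in sip53 and 20.24% in siEAF2+sip53. A floor of 3 reads was 0.1637 to 0.177 CPM.

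Both targeted transcripts were lower in the libraries that received their siRNA. EAF2 (chromosome 3, 121835183 to 121886526, GRCh38) was at 12.6 CPM in siCont, 10.5 in mock, 5.08 in siEAF2 and 2.95 in siEAF2+sip53. The siEAF2 library held 40.4% of the siCont level (95% counting interval of the ratio 0.313 to 0.518) and the siEAF2+sip53 library 23.5% (0.171 to 0.318). EAF2 was also lower in sip53, at 7.74 CPM or 61.5% of siCont (0.492 to 0.768). TP53 (chromosome 17, 7661779 to 7687550) was at 112 CPM in siCont, 106 in mock and 100 in siEAF2, against 42.4 in sip53 and 43.3 in siEAF2+sip53. The sip53 library held 38.0% of the siCont level (0.348 to 0.414). In the additive edgeR quasi-likelihood model, EAF2 fell with EAF2 siRNA (log2 fold change -1.34, SE 0.16, adjusted p = 0.0296), and TP53 fell with TP53 siRNA (-1.30, SE 0.08, adjusted p = 0.0141). The EAF2 call was kept in 7 of 14 alternatives, at log2 fold changes from -1.34 to -1.33, and over all alternatives the log2 fold change lay between -1.38 and -1.18. Its adjusted p was 0.149 by edgeR with mock in place of siCont, in a range of 0.0013 to 0.149 over the alternatives. The TP53 siRNA effect on EAF2 did not pass (-0.73, SE 0.16, adjusted p = 0.108).

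**Figure D1:**
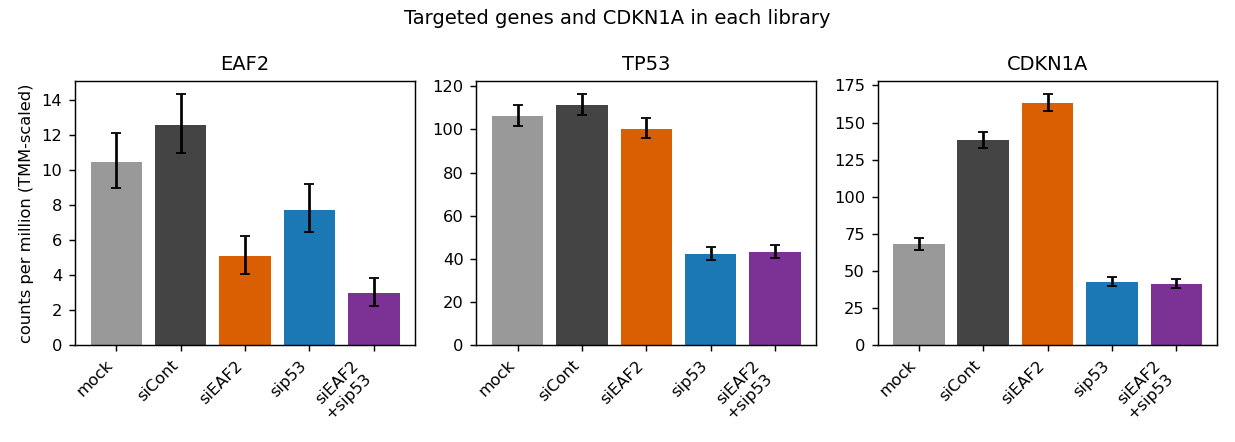
Bars give TMM-scaled CPM of EAF2, TP53 and CDKN1A in each of the 5 libraries, and error bars are exact 95% Poisson intervals of the reads (counting error only, 1 library per group). EAF2 is lowest with both siRNAs at 2.95, TP53 is near 43 in both libraries with TP53 siRNA, and CDKN1A is at 68.2 in mock against 138 in siCont.

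EAF2 siRNA was accompanied by a rise of interferon-stimulated genes, with and without TP53 siRNA. Of 34 members tested, 15 rose and 0 fell by edgeR with Benjamini-Hochberg adjustment, and 22 rose and 0 fell when adjusted over the list alone, while DESeq2 and limma called 9 and 14 over all genes. OASL, an oligoadenylate synthetase-like antiviral protein (chromosome 12, 121019111 to 121039242), was at 0.464 CPM in siCont, 0.469 in sip53 and 1.42 in mock, against 24.5 in siEAF2 and 18.5 in siEAF2+sip53 (log2 fold change 5.51, SE 0.20, adjusted p = 0.000567). OAS2, which makes the activator of RNase L, rose by 4.48 on the log2 scale (SE 0.26), and IFIT3 and IFIT2, antiviral proteins that bind RNA, by 4.27 (SE 0.19) and 4.20 (SE 0.22). The chemokine CXCL10, which is outside the list, had 118 reads in siEAF2 and siEAF2+sip53 together and 1 read in siCont and sip53 together, a ratio of 112 with a counting interval of 19.7 to 4450, and 3 reads in mock. The list's median EAF2 siRNA effect was 0.87 over 33 measured members, at percentile 100 of matched random lists. The median log2 ratio was 1.06 for siEAF2 over siCont, 0.74 for siEAF2+sip53 over sip53 and 0.12 for mock over siCont. In sip53, where EAF2 was at 61.5% of siCont, the list's median ratio to siCont was -0.00227. The macrophage marker CD68 was at 28.7 CPM in siEAF2 and 22.1 in siCont. With mock in place of siCont the list's median was 0.64, and 10 of its members passed. The log2 fold changes were then 4.55 for OASL, 3.82 for OAS2, 3.63 for IFIT3, 3.90 for IFIT2 and 5.13 for CXCL10.

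**Figure D2:**
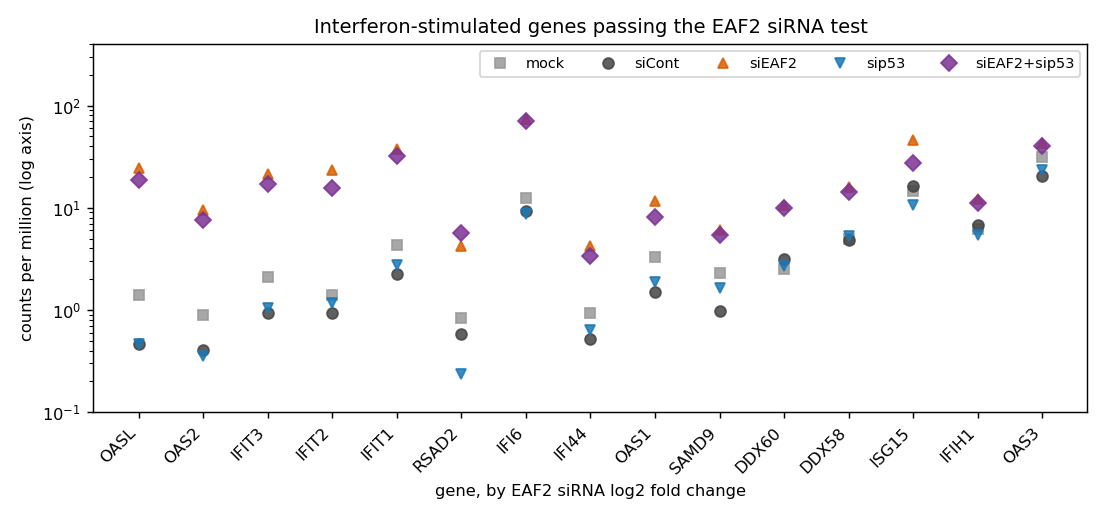
Points give CPM on a log axis in each of the 5 libraries for the 15 interferon-stimulated genes that passed the EAF2 siRNA test, ordered by log2 fold change. In each gene the siEAF2 and siEAF2+sip53 points lie above the siCont and sip53 points, as for OASL at 24.5 and 18.5 against 0.464 and 0.469.

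Over all 15365 genes tested, 87 were higher and 98 were lower with EAF2 siRNA, and 177 of these 185 are protein-coding. Outside the genes with shared or alternate-haplotype sequence, the largest falls with a symbol after EAF2 were in AIF1L, an actin-binding protein (log2 fold change -1.33, SE 0.11, adjusted p = 0.0139), SPON2, a secreted matrix protein (-1.24, SE 0.07), and S1PR3, a sphingosine 1-phosphate receptor (-1.14, SE 0.09). SUSD2 (-1.10), the endoplasmic reticulum co-chaperone DNAJB9 (-1.09) and the orphan receptor GPRC5B (-1.07) followed. SPON2 was at 425 CPM in siCont and 186 in siEAF2, but also at 247 in mock. SUSD2 was at 9.85 CPM in siCont, 4.24 in siEAF2 and 4.67 in mock. S1PR3 (38.8 in mock against 57.9 in siCont), GPRC5B (17.5 against 23.4) and AIF1L (78.7 against 89.0) were also lower in mock. DNAJB9 was higher there (52.65 against 45.65). IFIT3, IFIT2, OASL, OAS2 and CXCL10 were among the 10 largest rises. The remaining 5 were genes with shared or alternate-haplotype sequence. The pseudogenes PFN1P1, RPL7P9 and RPL15P3 had 0 reads without EAF2 siRNA and were at least 119-fold, 18.6-fold and 16.4-fold higher with it, against a floor of 3 reads over the group. PFN1P1 had 30 reads in siEAF2 and 348 in siEAF2+sip53, so its bound rests mostly on the latter library. RPL7P9 had 15 and 44, and RPL15P3 25 and 27. CFB (48 reads in siEAF2 and siEAF2+sip53 against 1 in siCont and sip53, ratio 45.5, interval 7.78 to 1830) and UGT2B11 (59 against 3, ratio 18.6, interval 6.07 to 93.0) had few reads, with 1 and 4 in mock. Among the falls, TMEM189-UBE2V1 was at least 18.3-fold lower with 99.0% of its words shared, ZNF320 (-1.02) shared 79.0%, and KANSL1 (-1.40) lies in the chromosome 17 region with alternate haplotypes. The count of calls moved with the processing. With mock in place of siCont 20 genes were higher and 5 lower, and 23 of the 185 still passed. Among the falls named here AIF1L and DNAJB9 did, and SPON2 (-0.84), S1PR3 (-0.86), SUSD2 (-0.58) and GPRC5B (-0.86) did not.

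With EAF2 siRNA, 2 of 24 unfolded protein and integrated stress response genes rose and 3 fell, and 8 rose and 5 fell when adjusted over the list alone, while DESeq2 and limma called 6 and 5. CHAC1, a glutathione-degrading enzyme induced through ATF4 (log2 fold change 1.79, SE 0.27), and the transcription factor ATF3 (1.13, SE 0.13) rose. The endoplasmic reticulum chaperones DNAJB9 (-1.09, SE 0.09), PDIA4 (-0.47, SE 0.07) and HSPA5 (-0.45, SE 0.06) fell. Of these 5, 3 passed with mock in place of siCont, and PDIA4 (-0.56) and HSPA5 (-0.52) did not. CHAC1 was at 25.3 CPM with both siRNAs, against 7.20 in siEAF2, 5.22 in sip53 and 3.42 in siCont.

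Of 30 androgen response genes, 3 rose and 1 fell with EAF2 siRNA, and 8 rose and 1 fell when adjusted over the list alone, while DESeq2 and limma called 6 and 4. The risers were STEAP4, a metalloreductase (1.16, SE 0.14), NDRG1 (0.84, SE 0.10) and ACSL3, a fatty acid ligase (0.47, SE 0.07), and the cation channel TRPM8 fell (-0.57, SE 0.07). The list's median was -0.00428, and its sign turned with scaling by total counts (0.00925). NDRG1, at 885 CPM in siCont and 1376 in siEAF2, was also the only 1 of 18 hypoxia and angiogenesis genes to pass. TP53INP1 (-0.53, SE 0.07) was the only 1 of 37 p53 targets to pass the EAF2 siRNA test, and 2 rose and 2 fell when adjusted over the list alone, while DESeq2 and limma called 2 and 1. FN1, which encodes fibronectin, fell (-0.61, SE 0.06) among 13 epithelial to mesenchymal transition genes, INSIG1 rose (0.44, SE 0.06) among 23 cholesterol synthesis genes, and HIST1H1C rose (0.69, SE 0.08) among 14 histone genes. Adjusted over the list alone, 1 was higher and 3 lower, 1 higher and 0 lower, and 1 higher and 0 lower. For hypoxia and angiogenesis this was 2 higher and 1 lower. STEAP4 still passed with mock in place of siCont, while NDRG1 (0.67), ACSL3 (0.58), TRPM8 (-0.57), TP53INP1 (-0.33), FN1 (-0.63), INSIG1 (0.39) and HIST1H1C (0.67) did not, with their log2 fold changes there in brackets.

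No cell cycle gene passed the EAF2 siRNA test, although all 44 had a negative effect. By edgeR 0 of 44 passed over all genes, 26 had an unadjusted p below 0.05, 7 were lower when adjusted over the list alone, and DESeq2 and limma called 1 and 0. The list's median was -0.34, at percentile 0. The ratio of siEAF2 over siCont had a median of -0.08, with 33 genes below 0 and 11 above. That of siEAF2+sip53 over sip53 had a median of -0.62, with 44 below 0, so 33 of 44 were lower in both backgrounds. The difference between backgrounds was not tested, and the additive model counts it as noise, which makes calls less likely. UBE2C was at -0.62 (SE 0.16), CDC20 at -0.59 (SE 0.14), PLK1 at -0.58 (SE 0.12) and MKI67, the Ki-67 antigen, at -0.57 (SE 0.10). Of 25 STAT3 targets, 0 passed for EAF2 siRNA, with 6 at an unadjusted p below 0.05, 0 adjusted over the list alone, and DESeq2 and limma calling 1 and 0. For TP53 siRNA 0 passed as well, with 5 unadjusted, 0 over the list alone and 0 by DESeq2 and by limma. Their medians were -0.03 and 0.06.

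With TP53 siRNA p53 target genes were lower on balance, but 3 of 37 passed over all genes by edgeR, and 0 with mock in place of siCont. CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), was at 138 CPM in siCont and 163 in siEAF2, against 42.8 in sip53 and 41.3 in siEAF2+sip53 (edgeR log2 fold change -1.83, SE 0.09, adjusted p = 0.00756). PHLDA3, an inhibitor of AKT (-1.10, SE 0.11), and RPS27L, a ribosomal protein paralog (-0.82, SE 0.09), also fell. Of 37 p53 targets, 3 fell and 0 rose, 16 fell and 0 rose when adjusted over the list alone, DESeq2 and limma called 5 and 3, and 30 were lower in both backgrounds. SPATA18 (-1.60, SE 0.23) and BTG2 (-0.90, SE 0.11) passed over the list alone. The list's median was -0.31, at percentile 0. The median of sip53 over siCont was -0.25, and that of mock over siCont was -0.18, also at percentile 0. That of sip53 over mock was -0.155. CDKN1A in mock was at 68.2 CPM, 49.4% of siCont. With mock as the control its TP53 siRNA effect was -1.33 with an edgeR adjusted p of 0.398, in a range of 2.69e-37 (DESeq2) to 0.447 over the alternatives.

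Over all genes, 3 were higher and 24 lower with TP53 siRNA. These counts moved widely with the processing, to 20 and 118 by DESeq2 and 99 and 291 with scaling by total counts. Next to the p53 targets and TP53, the falls included MANEAL (-1.05, SE 0.11), TMEM127 (adjusted p = 0.048, at 53.1 CPM in siCont and 30.6 in sip53), LEPROT (-0.91, SE 0.09) and PPP6R1 (-0.89, SE 0.07), which lies in the chromosome 19 region with alternate haplotypes. ATXN7 (-4.32), TAP2 (-3.02) and KANSL1 (-1.83) are genes with shared or alternate-haplotype sequence. So are the risers: FTH1P2 (2.57, SE 0.24), which the rule names, and PFN1P1 and AC137834.1, chosen after their values were seen. With mock in place of siCont 0 of the 27 passed by edgeR. ATXN7 was not tested there, and the other 26 all kept their sign. TP53 itself had an edgeR adjusted p of 0.0566 there, in a range of 4.35e-16 (DESeq2) to 0.132 over the alternatives.

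Androgen response genes were lower on balance with TP53 siRNA, but none passed over all genes. By edgeR 0 of 30 passed, 21 had an unadjusted p below 0.05, 1 was higher and 17 were lower when adjusted over the list alone, and DESeq2 and limma called 13 and 0. The median was -0.28 at percentile 0, and 24 of 29 were lower in both backgrounds. STEAP4 was at -0.82 (SE 0.14), CENPN at -0.51 (SE 0.07) and the low gene ORM1 at -1.51 (SE 0.43). Of 41 ribosomal protein genes 0 passed, 26 had an unadjusted p below 0.05, 21 were lower over the list alone, and DESeq2 and limma called 5 and 0. Their median was -0.19, with RPL13A at -0.38 (SE 0.06). Of 24 stress-response genes 0 passed, 10 had an unadjusted p below 0.05, 7 were higher over the list alone, and DESeq2 and limma called 2 and 0, with CHAC1 at 1.38 (SE 0.27) and PHGDH at 0.49 (SE 0.06).

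**Figure D3:**
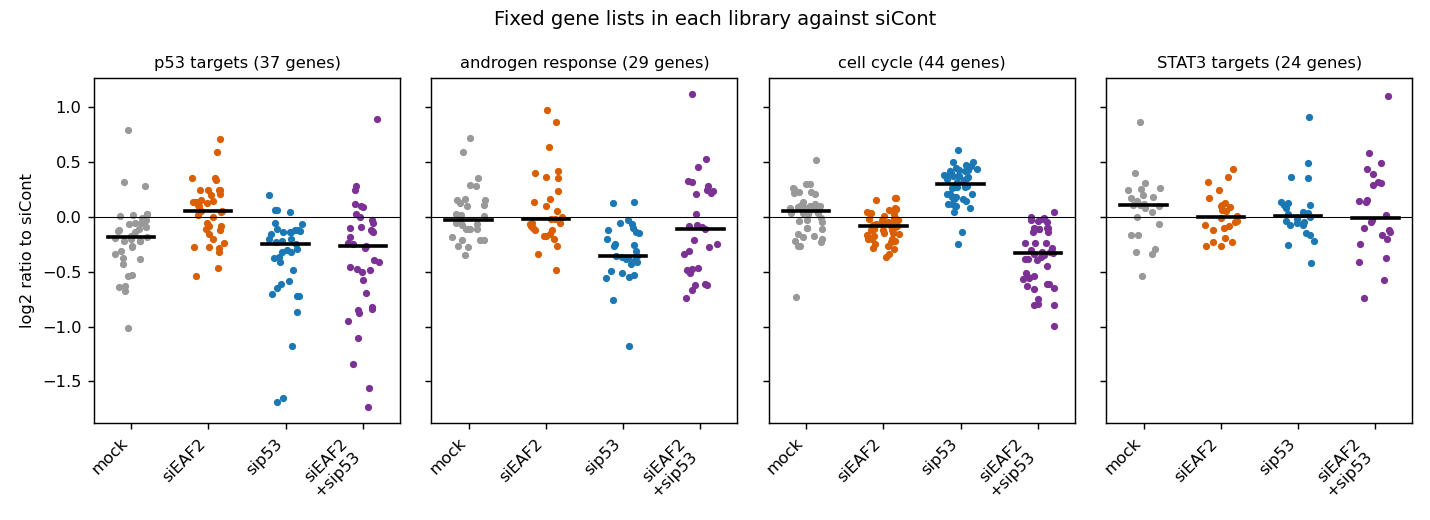
Points are genes and black bars medians of the log2 ratio to siCont in mock, siEAF2, sip53 and siEAF2+sip53, for 37 p53 targets, 29 androgen response, 44 cell cycle and 24 STAT3 target genes. The p53 target median is -0.25 in sip53 and -0.18 in mock, and the cell cycle median is 0.30 in sip53 and -0.34 with both siRNAs.

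Cell cycle genes had a median departure from additivity of -0.57, at percentile 0, which was not tested and rests on 1 culture per group. Their median log2 ratio to siCont was -0.08 in siEAF2, 0.30 in sip53 and -0.34 in siEAF2+sip53. MKI67 was at 352 CPM in siCont, 272 in siEAF2, 486 in sip53 and 281 with both. Of the 44 genes, 42 were higher in sip53 than in siCont and 43 were lower with both siRNAs than in siCont. DNA repair genes had medians of 0.17 in sip53 and -0.19 with both over siCont, and a departure of -0.32. The 4 libraries leave no degree of freedom to test a departure.

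Over all 13934 genes compared, 106 were at least 2-fold higher and 99 lower in siEAF2 than in siCont, 94 and 82 in sip53, 211 and 165 in siEAF2+sip53, and 109 and 75 in mock. The siEAF2 and siEAF2+sip53 libraries shared OASL, IFIT2, IFIT3, IFIT1 and IFI6 among their 6 highest genes. Their other entries were TRIM49D2 (100% shared words) and FTH1P2 (56.8%). The lowest in siEAF2 were HIST2H2AA3 (-1.92), RGPD8 (-1.60), EIF3CL (-1.60) and DAXX (-1.55), which have shared or alternate-haplotype sequence, PORCN (-1.40) and EAF2 (-1.29). With both siRNAs, KANSL1 (-3.36), TAP2 (-2.49), EAF2 (-2.05), CDKN1A (-1.74), TRIM27 (-1.71) and NXT2 (-1.58) were lowest, and KANSL1, TAP2 and TRIM27 have shared or alternate-haplotype sequence. In sip53, 10 of the 12 genes at the ends have shared or alternate-haplotype sequence, and the exceptions were CDKN1A (-1.69) and STK11IP (1.69). STK11IP was raised to a similar degree over siCont in siEAF2 (1.695) and in siEAF2+sip53 (1.82), and less in mock (0.41). The pseudogene RPL7P1 had 0 reads in sip53 and 219 in siCont, at least 72.2-fold lower against a floor of 3 reads in that library. It had 133 reads in siEAF2+sip53, which also received TP53 siRNA, 216 in siEAF2 and 56 in mock. In mock, 11 of 12 have shared or alternate-haplotype sequence, led by FTH1P2 (2.09) and KANSL1 (-2.46), and GLIS2 (-1.93) was the exception. Of the 10 genes with the extreme departures from additivity, 9 were of that class, and GLIS2 (-1.72) was again the exception.

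Across genes, the EAF2 siRNA ratio without TP53 siRNA correlated with that in its presence at r = 0.354, and the TP53 siRNA ratios in the 2 backgrounds at r = 0.256. The ratios in each pair share no library, simulated libraries with no effect gave 0.000612 and 0.00274, and genes are not independent replicates. With mock in place of siCont these were 0.203 and 0.0311. The EAF2 and TP53 effects correlated at r = 0.0966 (covariance 0.00946), against -0.0130 (covariance -0.000688) in simulated libraries. The simulated libraries were equally noisy, and unequal noise between libraries can also give a positive covariance. The standard deviation of log2 ratios to siCont was 0.465 in siEAF2+sip53, 0.366 in siEAF2 and 0.351 in sip53. The difference from simulation therefore cannot be read as a shared response. With mock in place of siCont this turned to -0.0305. For ratios that share no library, r was -0.113 (siEAF2 over siCont with sip53 over mock) and -0.173 (sip53 over siCont with siEAF2 over mock). The ratios siEAF2 over siCont and sip53 over siCont, which share the control, correlated at 0.308, below the 0.497 that unchanged libraries gave.

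**Figure D4:**
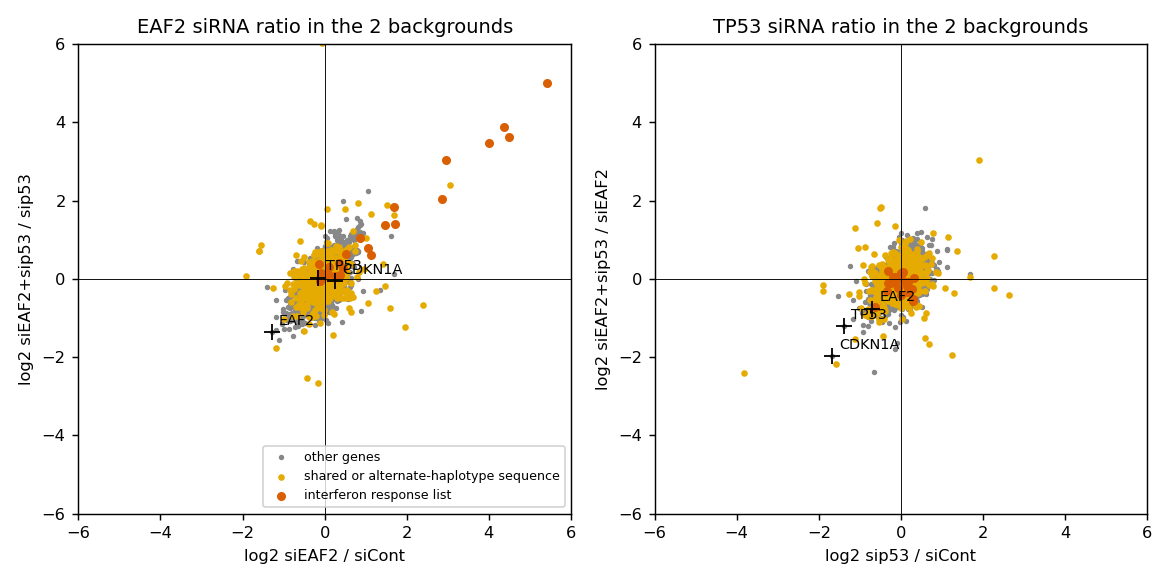
Each point is 1 of 11056 genes with a mean of at least 5 CPM, with the log2 ratio for EAF2 siRNA (left) or TP53 siRNA (right) without the other siRNA on the x axis and in its presence on the y axis; 3 genes in each panel lie outside the axes. OASL, an interferon gene, lies farthest to the right in the left panel at 5.42, and many of the points far from 0 on either axis are genes with shared or alternate-haplotype sequence.

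No marker of another cell type passed over all genes by edgeR, which does not tell whether such cells were present. A mean of 1 CPM was reached by 6 of 14 neuroendocrine, 3 of 11 basal prostate and 4 of 10 fibroblast and stroma markers. The highest of these were SYT4 at 190 CPM, ITGA6 at 41.1 and COL1A1 at 14.2. Among 18 testis germ cell genes 2 reached a mean of 1 CPM, the higher being ODF2L at 43.8 CPM, and 0 of 4 tested passed for either siRNA (0 unadjusted, and 0 by DESeq2 and limma). All 15 luminal prostate markers measured reached it, the highest being NKX3-1 at 1220 CPM, and the highest androgen response gene was KLK3 at 3530. These levels argue against testes, which the extraction text names, as the source of the RNA. Of 11 immune cell genes only CD68 reached a mean of 1 CPM over the 5 libraries, at 22.1 in siCont, 28.7 in siEAF2, 15.4 in sip53 and 22.1 with both. It did not pass over all genes (EAF2 siRNA 0.45, SE 0.09; TP53 siRNA -0.43, SE 0.09), and over the list alone 1 gene was higher with EAF2 siRNA and 2 were lower with TP53 siRNA. LYZ, a lysozyme of myeloid cells, was at 1.23 CPM in siEAF2 and 0.927 in siCont, and PTPRC, a leukocyte surface phosphatase, was between 0.177 and 0.383.

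The remaining lists held no gene that passed edgeR over all genes. For EAF2 siRNA, 15 super elongation complex genes had a median of 0.02 (3 at an unadjusted p below 0.05, 0 over the list alone, 0 by DESeq2 and by limma), with ELL2 at 0.26. Of 24 DNA repair genes, 8 had an unadjusted p below 0.05 and 0 passed over the list alone or by DESeq2 or limma, at a median of -0.21 (percentile 0). Luminal prostate markers (15 genes) had a median of -0.08, with 4 above 0 and 11 below. Of these, 6 were unadjusted, 2 were higher and 3 lower when adjusted over the list alone, and 1 passed by DESeq2 and 0 by limma. The acid phosphatase ACPP was at -0.88, while 1 other marker was higher by at least 1 on the log2 scale. Of 4 basal prostate markers, 3 were lower when adjusted over the list alone, 3 had an unadjusted p below 0.05 and 0 passed by DESeq2 or limma. Of 8 neuroendocrine markers 2 and of 5 fibroblast and stroma markers 1 had an unadjusted p below 0.05, with 0 by DESeq2 and limma, and COL1A1, at -0.59, was the only 1 of these to pass when adjusted over the list alone. The 41 ribosomal protein genes had a median of 0.05 (2 unadjusted) and the 13 genes of the mitochondrial genome one of -0.05 (0 unadjusted), with 0 over the list alone and 0 by DESeq2 and limma.

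For TP53 siRNA, edgeR called 0 of 34 interferon response genes (2 unadjusted, 0 by DESeq2 and limma), and ISG15, a ubiquitin-like antiviral protein, was lower when adjusted over the list alone (-0.69). Of 13 mitochondrial genome genes 0 passed, 10 had an unadjusted p below 0.05, 0 passed over the list alone, and DESeq2 and limma called 3 and 0, at a median of 0.19 (percentile 100). Of 15 super elongation complex genes 0 passed, 2 were unadjusted and also lower when adjusted over the list alone, and DESeq2 and limma called 1 and 0. Of 18 hypoxia and angiogenesis genes 0 passed, 6 were unadjusted, 3 were lower when adjusted over the list alone, and DESeq2 and limma called 1 and 0. Of 15 luminal prostate markers 0 passed, 5 were unadjusted, 1 (KRT8, -0.41) was lower when adjusted over the list alone, and DESeq2 and limma called 1 and 0. By edgeR, DESeq2 and limma 0 passed among 44 cell cycle genes (3 unadjusted), 23 cholesterol synthesis genes (3), 24 DNA repair genes (0), 13 epithelial to mesenchymal transition genes (0), 4 basal prostate markers (1), 8 neuroendocrine markers (1), 5 fibroblast and stroma markers (0) and 14 histone genes (2). Adjusted over the list alone, 1 basal prostate marker was higher, 1 histone gene was lower, and 0 passed in the other 6 of these lists.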

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

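The tests for leukocytes, for the EAF2 transcript against the siRNA duplex and for shared words outside the alternate-haplotype regions were chosen after the result was seen, the class of genes with shared or alternate-haplotype sequence was defined after the data were examined, and the value set against growth state was known with the pattern itself.

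The cell cycle list had medians on opposite sides of 0 for TP53 siRNA in the 2 backgrounds. Its median log2 ratio was 0.298 without EAF2 siRNA and -0.26 in its presence, a difference that was not tested. For the additive TP53 siRNA effect 0 of 44 genes passed edgeR, DESeq2 or limma, with 3 at an unadjusted p below 0.05 by edgeR. That effect averages the 2 backgrounds and counts the departure from additivity as noise. The 0 of 44 therefore cannot decide whether the ratios differ between backgrounds. An unusual siCont library is argued against, since the median departure from additivity was -0.523 with mock in its place. The list's median departure was -0.566 without mitochondrial and other abundant genes, a weak test since TMM scaling already limits their weight. The share of counts they take would shift all genes alike. TMM scaling holds the median departure over all genes near 0 (-0.00432), so that value cannot decide. With scaling by total counts, which leaves such a shift in, the median over all genes was -0.056. That is far smaller in size than the list's -0.571, which argues against such a shift as the whole of the list's departure. A different growth state of the separately transfected cultures may give the same value of -0.571, and with 1 culture per group it cannot be told apart from a response to the concurrent knockdown.

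DNA repair genes also had medians on opposite sides of 0, of 0.169 without and -0.145 with EAF2 siRNA, and this difference was not tested. DAXX, in the chromosome 6 region with alternate haplotypes, had TP53 siRNA log2 ratios of -1.12 and 1.30, also untested. SULT1A4, with 97.6% of its words shared, had EAF2 siRNA log2 ratios of 1.97 and -1.23 and TP53 siRNA log2 ratios of 1.26 and -1.94 without and with the other siRNA, also untested.

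Interferon-stimulated genes were higher in both libraries with EAF2 siRNA. Reads shared between paralogs are argued against, since 15 of the 15 called members had at most 20% shared words. Leukocytes mixed into these libraries are argued against, since 1 of 11 markers (CD68) reached a mean of 1 CPM there, while TYROBP was at 0 and PTPRC at most at 0.383. Whether lower EAF2 transcript or the siRNA duplex itself gave the response cannot be told apart: the list's median in sip53, where EAF2 was at 61.5% of siCont, was -0.00227, but that is 1 library, which also received TP53 siRNA, and a response to a stronger loss of EAF2 could remain unseen there.

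Large ratios between mock and siCont may come in part from reads shared between copies of a gene. Outside the alternate-haplotype regions and at a mean of at least 5 CPM, genes with over 20% shared words were 5.37 times as frequent among the 34 genes at least 2-fold apart as among all genes compared (52.9% against 9.85%). For the class that includes the regions the value was 3.95 (54.3% against 13.8%), but the regions were chosen from genes seen at the ends of these comparisons, so this leaves the part of alternate haplotypes open. No biological explanation was tested for these ratios.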

How the results depend on the processing

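Leaving out genes with shared or alternate-haplotype sequence was chosen after the data were examined. No paired analysis was possible because the groups share only the number 1. Depth limits genes near 3 reads, and the cause of the changes below was not tested. For EAF2 siRNA, 87 higher and 98 lower calls became 271 and 287 with scaling by total counts, 140 and 187 with no low-count filter, 258 and 395 at a mean of at least 5 CPM, 10 and 3 with length-scaled TPM counts, 20 and 5 with mock in place of siCont, 21 and 11 with mock added as a control, and 367 and 490 without genes of shared or alternate-haplotype sequence. With mock added and 1 library left out they ranged from 13 to 87 and from 5 to 98. The upper ends, 87 and 98, are from leaving out mock, which is the main fit to the 4 siRNA libraries again. Leaving out 1 of those 4 gave 13 to 25 higher and 5 to 15 lower (13 and 7 without siEAF2, 16 and 8 without sip53, 25 and 15 without siEAF2+sip53, 20 and 5 without siCont). For TP53 siRNA, 3 higher and 24 lower became 99 and 291 with total counts, 20 and 96 with no filter, 131 and 274 at 5 CPM, 20 and 118 with DESeq2, 0 and 0 with length-scaled TPM counts, 0 and 0 with mock in place of siCont, 0 and 2 with mock added, and 148 and 381 without shared or alternate-haplotype sequence; limma called 7 higher. With 1 library left out they ranged from 0 to 3 and from 0 to 24, where 24 is again the main fit, without mock. Leaving out 1 of the 4 siRNA libraries gave 0 to 3 higher and 0 to 4 lower (1 and 1 without siEAF2, 1 and 4 without sip53, 3 and 3 without siEAF2+sip53, 0 and 0 without siCont). Of the 185 EAF2 siRNA calls 7 passed in all 14 distinct alternatives (AIF1L, IFI6, IFIT1, IFIT2, IFIT3, ISG15 and OASL) and 23 in at least 10. Of the 27 TP53 siRNA calls 0 and 1 did. A gene removed before an alternative's test counts there as not passing. The 31 EAF2 siRNA and 8 TP53 siRNA calls with shared or alternate-haplotype sequence therefore could not pass in all 14.

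Genes at least 2-fold apart, higher and lower, changed as follows. With no low-count filter there were 767 and 1088 in siEAF2, 1298 and 1026 in sip53, 1129 and 1109 in siEAF2+sip53, 1263 and 973 in mock, and 1738 and 1784 departures from additivity. At a mean of 5 CPM these were 27 and 16, 14 and 19, 61 and 69, 22 and 17, and 27 and 28. With gene TPM they were 226 and 155 in siEAF2, 217 and 183 in sip53, 271 lower in siEAF2+sip53, 200 and 171 in mock, and 306 and 407 departures. Without shared or alternate-haplotype sequence they were 57 and 50, 43 and 25, 97 lower, 57 and 27, and 86 and 84. With mock in place of siCont 128 were lower in sip53 and 332 departures were higher.

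The correlation of EAF2 siRNA ratios between backgrounds was 0.553 at 5 CPM, 0.203 with mock in place of siCont, 0.226 with gene TPM and 0.534 without shared or alternate-haplotype sequence, and that of TP53 siRNA ratios 0.422, 0.0311, 0.154 and 0.403. The correlation of the EAF2 and TP53 effects turned from 0.0966 to -0.0305 with mock in place of siCont. The interferon median for EAF2 siRNA was 0.721 at 5 CPM, 0.639 with mock in place of siCont and 0.559 with gene TPM, and the basal prostate median -0.514 with mock and -0.285 with gene TPM. Among named genes, FTH1P2, which had passed, turned to -0.568 for EAF2 siRNA with mock added and sip53 or siEAF2+sip53 left out. The other sign changes were in effects that had not passed. For EAF2 siRNA, DAXX, EIF3CL and RGPD8 turned to 0.0244, 0.0645 and 0.129 with mock in place of siCont and to 0.878, 0.732 and 0.736 with mock added and siEAF2 left out, where HIST2H2AA3 turned to 0.0944, TP53 to 0.0389 and CDKN1A to -0.0421. For TP53 siRNA with mock added, TSEN34 and C6orf48 turned to -0.232 and -0.352 without sip53, and IFIT2 to 0.0046 without siEAF2 and 0.00598 without siEAF2+sip53. Of 903 values of named genes under the alternatives, 700 kept direction and side of the threshold, 173 no longer passed, 12 newly passed and 18 changed sign. Of 258 medians of lists within the central 95% of random lists, 26 changed sign.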

Other observations

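IFITM1, a gene outside the fixed interferon list that was chosen after its values were seen, was at 0.348 CPM in siCont, 10.7 in siEAF2, 1.52 in sip53 and 7.27 with both siRNAs (edgeR EAF2 siRNA log2 fold change 3.26, SE 0.49, adjusted p = 0.0452). With 35.3% of its words shared with other genes, its counts are uncertain, and it passed in 7 of 14 alternatives. An alternative that removed it before testing, as by leaving out genes with shared sequence, counts as not passing. Of the 15 called interferon genes of the list, 14 were lower with both siRNAs than with EAF2 siRNA alone and 12 were higher in mock than in siCont, and neither difference was tested.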
